A study of Citrus reticulata with 5 samples.

How the data were processed

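Total RNA from green flower buds and anthers of the 2 field-grown Ponkan genotypes was size-selected at 18 to 30 nt on a gel, ligated to adaptors, reverse transcribed, amplified and sequenced on an Illumina instrument, per the labels' protocols. The deposited files give, for each library, every distinct clean read with its length and its count, and the counts deposited by the authors are raw numbers of reads, not normalised. The adaptor trimming, quality filter and any aligner or genome build are not given in the sources used here. The label of the degradome library carries the small RNA protocol text, so its own construction is not described. No molecular identifiers are mentioned, so reads that are PCR copies cannot be told from independent molecules. Each of the 5 groups holds 1 library.

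Depth was the sum of the counts, from 20086455 to 23122966 reads per library. A sequence with 0 reads may have up to 3 counts at 95% confidence, which is 0.131 to 0.149 RPM in the small RNA libraries. A list of 59 sequences in 42 families, in 8 groups that include development, auxin, nutrient and copper, phasiRNA triggers, reproductive, silencing feedback and citrus families, was written from general knowledge before the data were examined, as was a list of 8 nuclear tRNAs. The sets of comparisons, alternatives and named families were fixed at the same time. Reads of 19 to 25 nt were assigned to the family with fewest mismatches, at most 2, with either end shifted by at most 2 bases, and reads tied between families were left out. In the text miR156 includes miR157, miR166 includes miR165 and miR171 includes miR170.

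Family counts were divided by all clean reads of the library. Ratios are log2 of reads per 1000000 clean reads (RPM) with the exact conditional binomial (Clopper-Pearson) 95% interval of 2 Poisson counts. A family was called higher or lower when it was at least 2-fold apart, had 100 or more reads in the higher library and had an interval that excluded equality. No p-value was computed, since each group has 1 library, and the calls compare these libraries, not the conditions. Distinct sequences of 20 to 24 nt were compared by the same limits without the interval. A list's median log2 ratio, over its families with 10 or more reads, was placed among 10000 random lists of the same size drawn from the 200 unlisted 20 to 22 nt sequences nearest in abundance. This describes the libraries and is not a test. The 2 genotype ratios were compared across tissues by their difference.

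The families named in the text follow a rule fixed before the data were examined: in a genotype comparison the 10 highest and 10 lowest called families, a fixed set of 15 families, and the 5 most abundant; in a tissue comparison the 5 highest and 5 lowest; for unlisted sequences the 5 highest and 5 lowest with 1000 or more reads; and for the degradome the 15 sites with most reads and sites of families named elsewhere. Members shown inside a family, miR398, miR408, miR168, miR393 and the 24 nt classes were chosen after their values were seen.

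The degradome was searched without a transcriptome. For each family with 100 or more reads, the listed sequences and the most abundant read gave probes complementary to miRNA positions 1 to 10, and the reads of tags that start with a probe were summed. The same was done for cuts after positions 7, 8, 9, 11 and 12, each with at most 10 bases. The background was 1000 shuffles of each family's probes, and a family needed 10 or more reads and more than the 95th percentile of the shuffles. The planned score of target sites was not run, because no transcriptome was used here. Probes of fewer than 10 bases match more tags by chance, so each register is set only against its own shuffles.

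Alternatives were scaling by the reads of the listed families or of 20 to 24 nt, TMM factors from edgeR 4.0.16 over the distinct sequences, exact or 1-mismatch matching, minimums of 10 or 1000 reads and a 4-fold limit. Sequences of 21 and 22 nt were called overlapping on both strands when 6 or more of the offsets within 6 bases, on each strand, held another sequence with a shared stretch of 15 bases. This minimum was chosen after the data were seen, when 8, 9 and 10 were also looked at; 8 is given as an alternative. The candidate coat protein, of citrus tristeza virus, was written from general knowledge after the data were seen, and reads were matched to it as words of 6 translated residues. A viroid sequence and degradome matches with 1 mismatch were also looked at and are not reported. The 5′ fragments of 8 nuclear and 22 organellar tRNAs, the second list written after some members had been seen, were reads that start at the first base with at most 1 mismatch, and 5.8S rRNA fragments were exact parts of a listed 5.8S sequence.

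The steps were tested on simulated data. Among the 23722 bud sequences, 100% of those seeded at 4-fold higher, 100% of those at 3-fold higher and 68.0% of those at 4-fold lower were called, and 0 unchanged ones. For the 17243 anther sequences these shares were 100%, 100% and 60.0%. The seeded lower sequences that were missed lay under the 100-read minimum in the higher library. The simulated counts held counting error only, and the interval was required, unlike in the comparison of distinct sequences. The 0 therefore gives no rate of false calls between real libraries. Family assignment recovered 100% of 1180 mutated reads, but these were made within the assignment limits, so this checks the code only. The degradome step recovered all of the 11 planted families, with 3 of the other families called. Each planted family had more reads than miR3950 (183) and the called families below it, so recovery at such lower numbers was not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and Biopython 1.88, and R 4.3.3, were used.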

Results

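Small RNAs were sequenced from the flowers of Ponkan mandarin (Citrus reticulata), comparing the seedy cultivar Egan No.1 (EG) with its male-sterile, seedless mutant Qianyang seedless (QS). The 4 small RNA libraries came from green flower buds of 2.5 to 3.5 mm and from anthers of blooming flowers, each from EG and from QS. Another library, a degradome that records the 5′ ends of cut mRNAs, was made from buds and anthers together. The EG bud library held 20086455 clean reads and the QS bud library 22932752. The EG anther library held 20564423 reads, the QS anther library 21774956 and the degradome 23122966. Each group was 1 library, so no difference below has a replicate check. All intervals cover counting error only, except the bootstrap intervals of medians. Those resample distinct sequences as if independent and cover no variation between libraries.

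The 24 nt class, which in plants is made mostly of siRNAs from repeats, was the largest in EG buds (40.1% of reads), QS buds (45.2%) and EG anthers (41.1%). In QS anthers the 24 nt class held 32.0% of reads, and the 22 nt class held 33.2%, the largest share there. This lead rested on miR167: its most abundant 22 nt sequences had 2179912 and 1465538 of the 7225135 reads of 22 nt, against 6972413 reads of 24 nt. In EG anthers the same sequences had 1158500 and 873638 of 4885683 reads of 22 nt. The 22 nt class held 19.8% in EG buds, 18.8% in QS buds and 23.8% in EG anthers. The ratio of 24 nt to 21 nt reads was 1.81 in EG buds (95% exact binomial interval 1.81 to 1.81) and 2.35 in QS buds (2.35 to 2.35). In anthers the order of the genotypes was the opposite, with 2.39 in EG (2.38 to 2.39) and 1.63 in QS (1.63 to 1.63). Counting each distinct sequence once gave 6.06 in EG anthers and 5.15 in QS anthers.

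**Figure D1:**
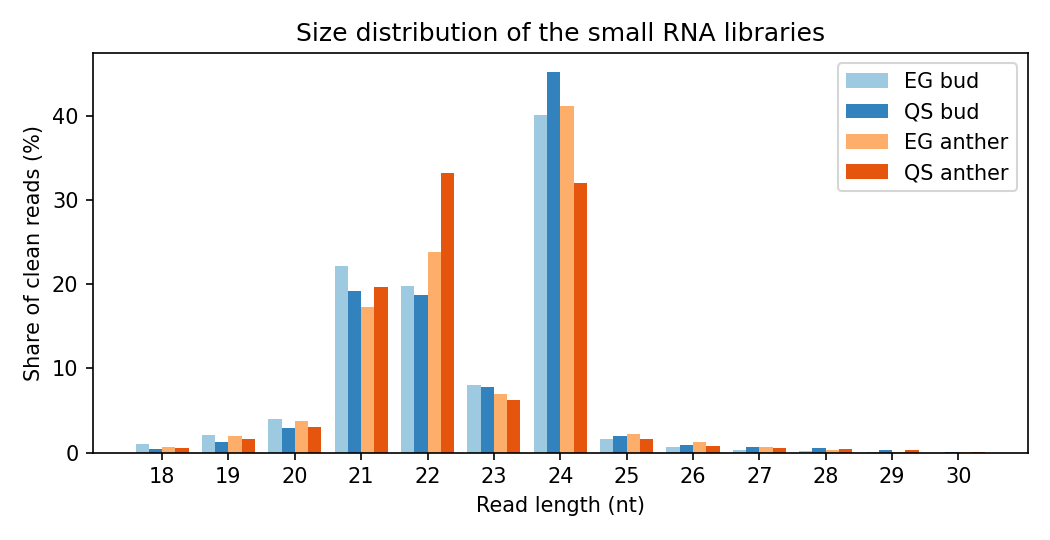
Share of clean reads (%) by read length (nt) in the 4 small RNA libraries, 1 bar per library. The 24 nt bar is the tallest in EG buds (40.1%), QS buds (45.2%) and EG anthers (41.1%), and in QS anthers the 22 nt bar (33.2%) stands slightly above the 24 nt bar (32.0%). The height of the 22 nt bar in QS anthers rests on abundant miR167 sequences.

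Reads of 42 listed miRNA and tasiRNA families made up 7.36% of the EG bud library, 7.61% of the QS bud library, 16.2% of the EG anther library and 23.4% of the QS anther library. In buds the citrus family miR3954 was the most abundant, with 42621 reads per 1000000 clean reads (RPM) in EG and 43348 in QS, which was 57.9% and 56.9% of the family reads. It was followed by miR166, a regulator of the HD-ZIP III leaf-polarity genes, with 18282 RPM in EG and 14675 in QS. In anthers miR167, which targets auxin response factors, was the most abundant, with 104502 RPM in EG and 176845 in QS, or 64.6% and 75.5% of the family reads. miR156, which targets SPL genes, reached 19424 RPM in EG anthers and 27812 in QS anthers.

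The first comparison asked which small RNA families differed between the seedless mutant and its seedy parent in green buds. Of the families with enough reads, 1 was higher and 2 were lower in QS. miR167 was 2.16-fold higher in QS (8759 against 4060 RPM, log2 ratio 1.11, interval 1.10 to 1.12). miR160, another family that targets auxin response factors, was 3.09-fold lower (38 against 103 reads, log2 ratio -1.63, interval -2.21 to -1.08). miR399, a phosphate-starvation miRNA, was 3.23-fold lower (112 against 317 reads, log2 ratio -1.69, interval -2.02 to -1.38). The difference in the family sum came from 22 nt members: TGAAGCTGCCAGCATGATCTTA had 58643 reads in EG and 158938 in QS, and TGAAGCTGCCAGCATGATCTGA had 6354 and 21198. Counted from the listed miR167 sequences alone, the direction turned, with a log2 ratio of -0.48.

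No other bud family was called. In the development list, none of the 9 families with 100 or more reads was 2-fold apart. miR159, which targets GAMYB-like genes of anther development, had a log2 ratio of 0.59 (0.50 to 0.68), and the related miR319 one of 0.56 (0.19 to 0.94). miR156 stood at 0.46, miR171 at -0.22, miR166 at -0.32 and miR172, which targets AP2-type floral genes, at -0.68 (-0.72 to -0.65). In the auxin list, 1 of 4 families with enough reads was higher and 1 was lower, while miR390 stood at 0.20 and the tasiARF siRNAs that it triggers at -0.57 (-0.61 to -0.54). miR168 was at 0.05 and miR3954 at 0.02. In the phasiRNA trigger list miR482 was at -0.12 (-0.65 to 0.41) with 64 and 61 reads, and miR2118 had 1 read in each library. In the reproductive list miR2275, a trigger of meiotic phasiRNAs in grasses, had 36 reads in QS and 9 in EG (log2 ratio 1.81, interval 0.73 to 3.05), and miR845 had 18 and 21, so neither reached the 100-read minimum. The copper miRNAs miR397 (log2 ratio 0.36), miR408 (0.29) and miR398 (8 against 3 reads) were not 2-fold apart with enough reads. The median of the citrus list (0.34) was at the 96.7 percentile of random lists matched on abundance, and that of the auxin list (0.20) at the 91.9 percentile. The random lists for these had medians of -0.25 and -0.21, so a list near 0 ranks above the middle. The nutrient and copper list was at the 89.6 percentile, development at 77.2, reproductive at 74.8, silencing feedback at 66.2 and phasiRNA triggers at 51.1. From the listed sequences alone the auxin median turned to -0.49, at the 18.1 percentile, and the nutrient and copper median turned from 0.27 to -0.69, at the 46.5 percentile. The development median turned from -0.07 to 0.12, at the 95.2 percentile.

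The same comparison in anthers, the tissue in which the mutant is sterile, gave 3 families higher and 2 lower in QS. miR397, a copper-responsive miRNA that targets laccases, was 5.51-fold higher in QS (318 against 57.7 RPM, log2 ratio 2.46, interval 2.37 to 2.55). miR477 was 2.42-fold higher (log2 ratio 1.28, interval 0.98 to 1.57) and the citrus family miR3951 2.15-fold higher (1.11, 1.04 to 1.17). The miR477 call was lost at up to 1 mismatch, since 321 of its 346 QS reads were 1 sequence at 2 mismatches from the listed one. miR535, a family related to miR156, was 4.96-fold lower (42.1 against 208.7 RPM, log2 ratio -2.31, interval -2.42 to -2.21). miR390 was 2.96-fold lower (21.7 against 64.4 RPM, log2 ratio -1.57, interval -1.72 to -1.41). Scaling to the reads of the listed families moved the median of all families from 0.10 to -0.43 and TMM factors moved it to 0.27. With the former, 1 family was higher and 6 were lower, and miR477 (0.74) and miR3951 (0.57) came under 2-fold.

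Of the other families in the nutrient and copper list, the copper miRNAs miR398 and miR408 had higher values in QS but too few reads to be called. miR398 had 71 reads in QS and 11 in EG (log2 ratio 2.61, interval 1.68 to 3.67), and miR408 had 51 and 6, with a log2 interval of 1.78 to 4.52. Others in the list did not go this way, with miR399 at -0.34, miR395 at -0.37 and miR827 at 0.01. miR2111, with 9 reads in QS and 7 in EG, stood at 0.28 (-1.31 to 1.94), within counting error. The median of the nutrient and copper list, over 6 families, was 1.24, at the 94.9 percentile of matched random lists. The citrus list was at the 68.0 percentile, phasiRNA triggers at 49.4, reproductive at 46.4, development at 35.5, auxin at 29.9 and silencing feedback at 20.7. In the development list none of 7 families was 2-fold apart. miR172 stood at 0.66 (0.63 to 0.69), miR156 at 0.52 (-0.016 with scaling to the listed families), miR171 at 0.27, miR166 at 0.10 and miR159 at 0.06, while miR319 had 7 and 8 reads. In the auxin list miR167 stood at 0.76, tasiARF at 0.04 (-0.11 to 0.19) and miR160 had 7 reads in each library. miR168 stood at 0.41, miR3954 at -0.62 and miR482 at 0.05. miR2275 had 2 reads in QS and 0 of 20564423 in EG, which allows up to 0.146 RPM, and miR2118 had 0 in both. miR845 had 19 and 21 reads.

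Members of a family did not all go the same way in anthers. Within miR156, TTGACGGAAGATAGAGAGCAC had 177382 reads in EG and 340116 in QS, a log2 ratio of 0.86. TTGACAGAAGAGAGTGAGCAC had 15007 and 2391 (-2.73), and CTGACAGAAGAGAGTGAGCAC had 13518 and 2288 (-2.65). Within miR171, TTGAGCCGCGCCAATATCACT had 173 reads in EG and 1 in QS. Counted from the listed sequences alone, miR156 was lower in QS anthers, with a log2 ratio of -2.27.

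**Figure D2:**
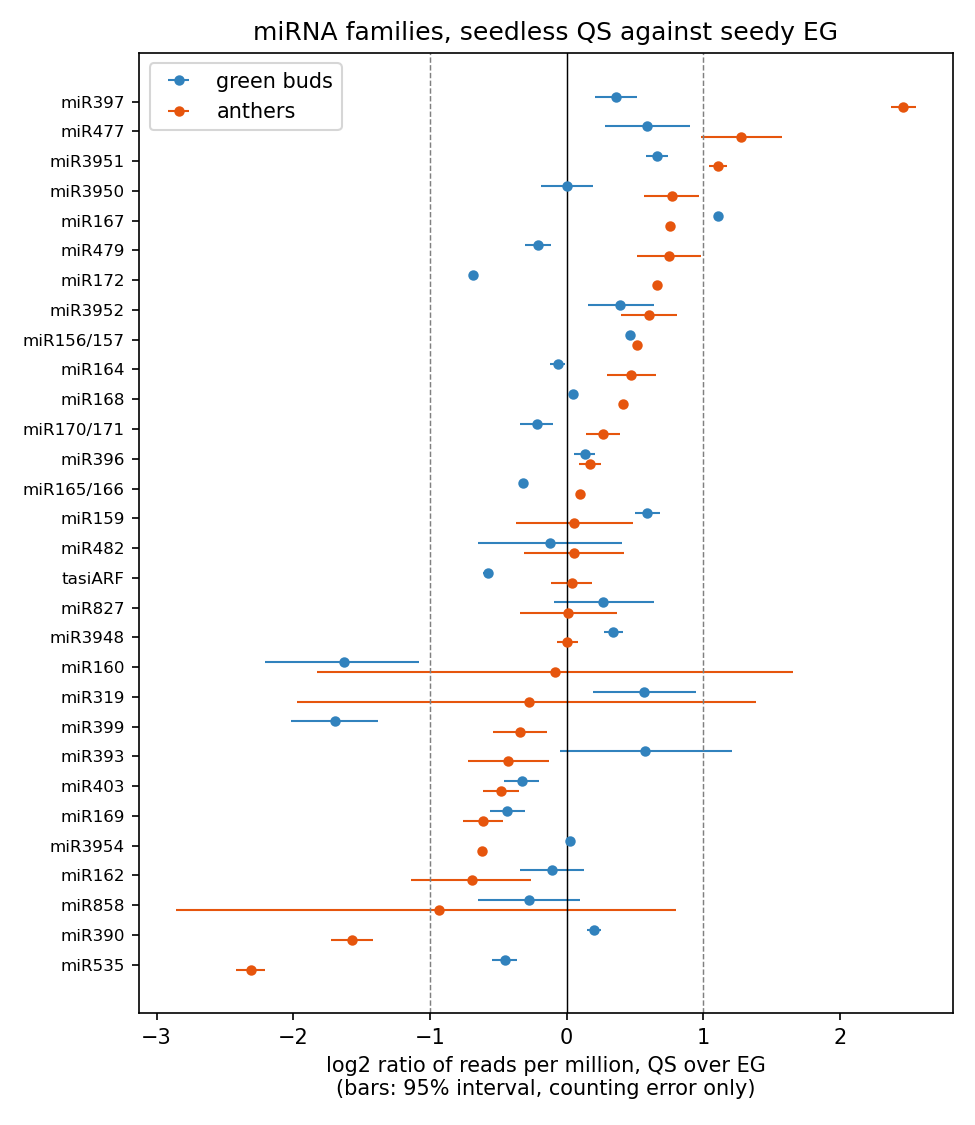
log2 ratio of RPM, QS over EG, for each family with 100 or more reads in a library, in green buds (blue) and anthers (orange), with 95% intervals that cover counting error only and dashed lines at 2-fold. miR397 (2.46) and miR535 (-2.31) lie farthest from 0 in anthers, and miR399 (-1.69) and miR160 (-1.63) in buds.

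The tissue comparison gives the background on which the genotype ratios stand, and since the labels give blooming flowers for the anthers and small buds for the rest, tissue and stage differ together. In EG, 3 families were higher and 10 lower in anthers than in buds. miR167 was 25.7-fold higher (log2 ratio 4.69), miR156 6.46-fold higher (2.69) and miR393, which targets auxin receptors, 5.89-fold higher (2.56). tasiARF was 21.1-fold lower (-4.40), miR159 17.5-fold lower (-4.13), miR160 15.1-fold lower (-3.91), miR858 14.3-fold lower (-3.84), and miR164, which targets NAC genes of organ boundaries, was also lower (-3.71). With edgeR's TMM factors, which moved the median of all families from -0.23 to 0.09, 6 families were higher and 10 lower. With scaling to the listed families the median was -1.37, and 3 were higher and 19 lower. From the listed sequences alone miR167 was lower in EG anthers than in buds (-2.08). The median of the auxin list, with 2 families higher and 3 lower, was -1.92, at the 6.11 percentile of matched random lists, and that of the nutrient and copper list was 0.37, at the 97.0 percentile, but turned to -0.92, at the 82.0 percentile, from the listed sequences alone.

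In QS, 7 families were higher and 10 lower in anthers than in buds. miR167 was 20.2-fold higher (4.34), miR397 8.42-fold higher (3.07), miR156 6.72-fold higher (2.75), miR399 3.61-fold higher (1.85, but 0.23 and no longer called with scaling to the listed families) and miR393 2.95-fold higher (1.56). miR159 was 25.3-fold lower (-4.66), miR858 22.6-fold lower (-4.50), tasiARF 13.8-fold lower (-3.79) and miR390 12.9-fold lower (-3.69), and miR319 was lower as well (-4.46). The median of the auxin list was -2.37, at the 0.26 percentile of matched random lists, but 2 of its families were higher and 2 lower, and the median is the value of miR160, which had 7 and 38 reads and was not called. The median of the nutrient and copper list was 1.40, at the 99.7 percentile, with 2 of its families called higher and miR395 (-0.76) and miR827 (-0.02) not higher. From the listed sequences alone it rested on 3 families and was at the 94.5 percentile. Scaling to the listed families turned miR172 (1.13 to -0.49), miR393 (to -0.06) and miR482 (1.15 to -0.47), and from the listed sequences alone miR167 (-1.02) and miR156 (-1.27) turned. TMM factors moved the median from -0.03 to 0.46, with 10 families higher and 8 lower, and scaling to the listed families moved it to -1.65, with 3 higher and 20 lower.

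No family was called, with 100 or more reads and 2-fold apart, in opposite directions in the 2 tissues, and none was called in the same direction in both. The largest shifts in the genotype ratio between tissues beyond counting error and with opposite signs were those of miR390 (0.20 in buds, -1.57 in anthers) and miR172 (-0.68 in buds, 0.66 in anthers). With scaling to the listed families the miR172 ratio in anthers was 0.13.

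Over all distinct sequences of 20 to 24 nt, 23722 had 100 or more reads in a bud library. Of these 5045 were 2-fold or more higher in QS and 5872 lower, together 46.0%. At a minimum of 10 reads the balance turned, with 66863 higher and 49984 lower. In anthers 17243 sequences had enough reads, of which 5868 were higher in QS and 4001 lower, together 57.2%, and at a minimum of 10 reads 60407 were higher and 61498 lower. The differences lay mainly in the shorter classes. In buds 72.1% of the 22 nt sequences and 59.7% of the 21 nt sequences were 2-fold apart, against 11.7% of the 24 nt sequences. In anthers these shares were 71.3% and 61.5%, against 30.2% of the 24 nt sequences. In buds 868 sequences of 24 nt were higher in QS and 63 lower, and in anthers 216 were higher and 963 lower. Among 11370 sequences with enough reads in both tissues, 2815 were higher in QS in both, where independent lists would share 1037, and 1109 were lower in both, where 310 would be shared. Overlapping sequences are not independent, and a sequence absent from 1 genotype is shared wherever it is read in both tissues. An excess over independent lists is therefore no test of agreement. The 5 highest and the 5 lowest unlisted sequences with 1000 or more reads were all of 21 or 22 nt. The highest in buds had 2678 reads in QS and 1 in EG, and the lowest had 3 and 1264. In anthers the highest had 4059 reads in QS and 1 in EG, and the lowest had 1 and 2534. These ranks set 0 reads to 3 counts, so that a sequence with 5846 reads in QS and 0 in EG (at least 1840-fold higher) and one with 0 and 2758 (at least 973-fold lower) rank behind them. Their bases are not given, since their source was not identified.

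A part of these sequences overlapped densely with others on both strands, as siRNAs cut from long double-stranded RNA do. Sequences of 21 and 22 nt of this kind made up 7.85% of reads in EG buds, 6.69% in QS buds, 5.09% in EG anthers and 7.34% in QS anthers. Without them and those matching a candidate protein, a setting chosen after seeing the data, 7412 of 18759 sequences in buds (39.5%) and 6843 of 13119 in anthers (52.2%) were 2-fold apart. This setting leaves in sequences that overlap densely on 1 strand only. The highest in anthers, with 12 offsets on its own strand and 4 on the other, is such a sequence. The shares left are therefore no measure of differences outside such siRNAs.

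The degradome tags were compared with the listed miRNAs to find mRNAs cut at the position where miRNAs guide cleavage, opposite positions 10 and 11 of the miRNA. For 15 of 31 families the tags whose first 10 bases complemented miRNA positions 1 to 10 outnumbered the 95th percentile of shuffled miRNAs. By the percentile alone 1.55 families would. On simulated tags without cut sites the step called 3 of the unplanted families (9.68%), so 1.55 may be too low. The neighbouring cut after position 11 gave 9 families, and cuts after positions 7, 8, 9 and 12 gave 4, 3, 3 and 3. The families were miR156 with 448 reads, miR3954 with 314, miR390 with 255, miR160 with 214, miR164 with 211, miR403 with 208, miR3950 with 183, miR3952 with 167, miR3951 with 145, miR169 with 127, miR172 with 123, tasiARF with 92, miR171 with 72, miR396 with 61 and miR166 with 14. For some of them other positions held more reads: miR3952 had 2506 and miR3950 1410 after position 11. miR3951 had 1766 after position 9, where probes of 9 bases match more tags by chance. These were above its shuffled reads (309), but its 21 distinct tags were not above the shuffled 32. At position 10 miR166 (14 reads, limit 13) and miR3951 (145, limit 136.1) passed narrowly. Over all families, position 11 held 4986 reads against 2948 at position 10. Counting each distinct tag once, 13 families were above their shuffled sequences at position 10, 9 at position 11 and 7 at position 8, without a minimum, a setting chosen after seeing the data. With a minimum of 10 distinct tags 5 families were left at position 10 and 5 at position 11, with 7 at position 8. miR167 had 10 reads in register, within the range of its shuffled sequences.

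**Figure D3:**
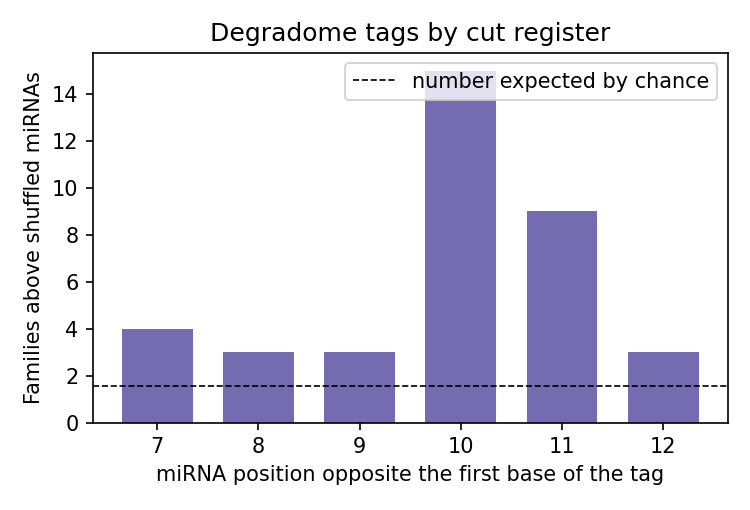
Number of miRNA families whose degradome tags exceed the 95th percentile of shuffled miRNAs, by the miRNA position opposite the first base of the tag. The dashed line marks the 1.55 families expected by the percentile alone, which may be too low, since simulated tags without cut sites gave 9.68% of unplanted families. The bar at position 10, the usual cut, reaches 15 of 31 families, and the bar at position 11 reaches 9.

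The single sites with most reads were tags that start with CTCTGTCCAAGCAATTAACA for miR3954 (273 reads), TGCTTCTCCAATTCTATTGA for miR164 (182), GTGAATCTAATGAGTTTCAA for miR403 (174), TCCTGAGCTTATTCTTCTTG for miR390 (155) and CTTCTGTCAATGCTCGATCG for miR156 (135). miR160 had GAGCCAGGCATGCCCAATAT (127) and GAGCCAGGCATGCTCAATTT (82), and miR3952 had AGGCCCTTCAACCTCGGAAA (106) and AGGCCCTTCAACTTCGACAA (61). miR390 also had TCCTGAGCTTTATGTAATGA (100), miR3951 had TCTTTATCTAATTTTCCTGC (94) and miR3950 had TGCAGAAAATACTTTTCCAA (65). Other miR156 tags were CTTCTGTCAAATCAACCATG (85), TCTTCTGTCATCACCACAGC (64) and TCTTCTGTCAATGCTCGATC (61), the last of which is the miR156 tag with 135 reads started 1 base earlier. The genes that hold these sites are not named, because no transcriptome was used here. For miR482, GTGGGCAAGAATACACAAGT had 35 reads, for miR172 TCAAGATTCTGACATGTTTT had 25, for miR171 GGCTCAATCACCAGGTTTTT had 32 and for tasiARF AGGTCAAGAAATATTAGGTT had 31.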

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

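All tests named here were chosen after the results were seen, except the median of anther-enriched sequences. The genotype ratio of miR172 had opposite signs in the 2 tissues, with an anther minus bud difference of 1.35 on the log2 scale, and that of miR390 differed by -1.77; neither difference was tested. A 3′ RACE adaptor made up 9.16% of the degradome reads, outside the small RNA comparisons. The summed 5′ fragments of the organellar tRNAs, also outside those comparisons, had a log2 ratio of -2.24 in anthers, with 8 of 12 tRNAs lower in QS and 0 higher, against 0.90 in buds, where 2 of 13 were higher and 1 lower with a median of -0.04; 5.8S rRNA fragments had -0.87 in anthers.

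There were 1806 sequences of 21 and 22 nt with 100 or more reads in each QS library and none in the EG libraries. Lower depth in EG is argued against, since the EG libraries held 90.9% as many reads as the QS libraries. Reads from a virus carried by the trees may account for some of them, in a share that was not measured. Of the QS-only sequences 3.21% matched coat protein words of citrus tristeza virus, against 1.52% of evenly read ones. Only the coat protein was matched, so these values do not give how much of either set is viral. Over all small RNA libraries 96.3% of the words were found, against at most 3.67% for 100 shuffled proteins, which does not place them in the QS-only set. Matching reads made up 0.44% of reads in EG buds, 0.41% in QS buds, 0.28% in EG anthers and 0.44% in QS anthers. Such reads were thus present in both genotypes, and their presence alone cannot account for sequences absent from EG. Of the EG-only sequences, only 150 in number, 0.67% matched. Close variants of sequences read in EG stay open, as 48.6% had a relative at 1 or 2 mismatches (83.3% of the EG-only ones had a relative in QS), and a difference between the genotypes themselves was not tested.

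miR535 and miR390 were lower in QS anthers. Dilution by miR167 reads is argued against, since without these reads in the totals the log2 ratios were -2.19 for miR535 and -1.45 for miR390. A general loss of anther-enriched RNA is argued against for miR390, which was lower in anthers than in buds of EG (-1.92). The median log2 ratio of 1932 sequences at least 4-fold enriched in anthers, by the geometric mean over both genotypes, was 0.22 (bootstrap interval 0.11 to 0.29). The others had 0.24. The median of the enriched set lay above the limit set beforehand for a loss. However, a sequence lost in QS anthers needs a higher enrichment in EG to enter the set, so the median cannot decide the question. Of the enriched set 34.2% were 2-fold or more lower in QS, against 21.9% of the others. For miR535 the question stays open, because miR535, at 0.93 between EG anthers and buds, is not among such sequences and the set does not cover it. A genotype difference was not tested.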

How the results depend on the processing

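The alternatives that leave out overlapping sequences or the minimum of distinct tags were chosen after the data were seen. For 38 called family results the other scalings and exact sequences gave 144 alternatives, with no read minimum applied. Of these 130 kept direction and the 2-fold limit, 7 came under it and 7 turned. Scaling to 20 to 24 nt gave 38 of those kept and hardly moved any ratio, so it tested little. Changed mismatches, read minimums and the 4-fold limit are not in this count. With exactly listed sequences miR167 turned in buds (-0.48), between tissues in EG (-2.08) and in QS (-1.02), and miR156 in QS (-1.27), because the abundant members are not the listed sequences. With scaling to the listed families miR172 (-0.49), miR393 (-0.059) and miR482 (-0.47) turned between tissues in QS, where miR167 alone made up 75.5% of the listed reads of the QS anthers. The number of families in buds was 0 with exact sequences, where miR160 (-1.82) and miR399 (-1.47) stayed 2-fold apart under the read minimum, 1 at a minimum of 1000 reads and 0 at 4-fold, and the miR160 call was also lost at up to 1 mismatch. In anthers it was 8 at a minimum of 10 reads and 2 at 4-fold, and the miR477 call was lost at up to 1 mismatch. Between tissues it was 22 in EG with scaling to the listed families, and in QS 11 with exact sequences, 11 at 1000 reads and 11 at 4-fold. The 24 to 21 nt ratio in EG buds, QS buds, EG anthers and QS anthers was 4.40, 4.94, 6.06 and 5.15 with distinct sequences once, 1.47, 2.0, 1.82 and 1.22 without single reads, and 2.25, 2.88, 3.01 and 2.06 without the 100 most abundant; the cause was not tested. Sequences 2-fold apart numbered 116847 in buds and 121905 in anthers at a minimum of 10 reads and 384 and 458 at 1000, as more or fewer are compared. Without sequences that overlap on both strands at 8 or more offsets, or match the coat protein, they numbered 8759 and 7972. Of 24 list medians 8 turned with exact sequences, and of 28 with TMM factors 2 turned. The degradome gave 5 families with 10 or more distinct tags and 13 without that minimum, so most of the loss came from the minimum. The target score alternative was not run. A model of genotype with tissue as a block was not fitted.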

Other observations

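The tests of miR167 scaling and of siRNAs at cut positions were chosen after the results were seen. In anthers, fragments of mitochondrial trnfM had 59194 reads in EG and 7078 in QS, those of plastid trnN 10110 and 238, and those of plastid trnH 82949 and 20506. Of 7 nuclear tRNAs with enough reads, tRNA-Ala (-1.46) and tRNA-Val (-1.52) were lower in QS anthers by log2 ratio, and tRNA-His was higher, with 1880 reads in EG and 11257 in QS. Summed nuclear tRNA fragments had a log2 ratio of -0.76. In buds mitochondrial trnfM fragments had 7977 reads in EG and 27812 in QS.

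miR167 was higher in QS buds. A scaling factor moves all families of a library alike, while the median of all families in buds was 0.05, against 1.11 for miR167. Scaling alone therefore does not account for the gap between miR167 and the other families. Whether scaling raised the level of miR167 itself stays open. The 4 scalings tried hardly differed in buds, with a lowest log2 ratio of 1.06, and so could not test it. More anther tissue in the QS bud library cannot be told apart from a genotype difference. It would raise miR167, 25.7-fold higher in EG anthers and 20.2-fold in QS anthers, more than sequences enriched 4-fold. The median of the 82 unlisted anther-enriched sequences was 0.0058 above that of the others, with a bootstrap interval of their median of -0.25 to 0.41. Of these sequences 24.4% were 2-fold or more higher in QS buds, against 7.74% of the others, and 7.32% were lower, against 20.6%. Of 3 family members outside miR167 with 500 or more bud reads and at least 4-fold enriched in anthers of both genotypes, 2 were lower in QS buds, both end variants of the same miR156 sequence, while GTGACAGAAGATAGAGAGCGC of miR156, 4-fold enriched in EG (2.39) but not in QS (1.65), was higher (1.05).

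siRNAs made from the cut products of miRNA targets may be present at few sites: 2 of 51 sites started 21 nt small RNAs with 100 or more reads, where sets of other tags had a median of 0 and at most 2. At the miR3954 site these had 417 reads in EG buds, 534 in QS buds, 192 in EG anthers and 299 in QS anthers. At the miR482 site they had 789, 654, 24 and 21, but the degradome reads of miR482 did not exceed its shuffled sequences, so this cut itself is not supported.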
